A study of Saccharomyces cerevisiae with 16 samples.

How the data were processed

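Protein fragments were tested for transcriptional activation in budding yeast. Each fragment was carried by a synthetic transcription factor that had been integrated in the haploid strain DHY211, and the pool was mated to a strain with a GFP reporter. Cells received β-estradiol for 4 h and were separated by FACS into 8 gates of GFP level, after which barcodes were sequenced from genomic DNA. The labels give 16 libraries, 8 gates in each of 2 sorts, with 1000000 cells per gate in the larger sort (replicate 1) and 500000 in the smaller (replicate 2). Each gate was a group of 2 samples. The labels do not say that the sorts came from separate cultures. The limma errors and p-values below measure the spread between these 2 sorts, which may be technical. The permutation and sign-flip p-values and the bootstrap and binomial intervals rest on regions instead. They treat regions as independent and do not measure the spread between sorts.

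The fragment table gives, per the file headers, an activity and a read number for each DNA sequence and sort. The deposited activity is a score, and its formula is not given in the sources used here. It lies between 379 and 17998, the lowest and highest of the 8 commonest values among barcode entries. These 8 were taken as the values of the 8 gates. The eighth was 28.3 times as common as the ninth in the larger sort and 4.78 times in the smaller. A mean of gate values weighted by the share of reads in each gate would have these bounds, but such a weighting was not tested. The GFP unit, the read parser and the scaling of gates are likewise not given in the sources used here. The read number appears to be a total over the 8 gates of a sort. Since no read number per gate was at hand, the test for a trend over gates that had been laid down before the data were examined was not run. A further 12 columns of activities and reads, 6 in each table, match none of the 16 samples by name and were not used here.

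A table by fragment and barcode, with 4047513 entries, was used only to find the 8 gate values and for checks. Its read numbers add up to 32.6 times the fragment totals in the larger sort and 19.8 times in the smaller. The planned permutation over barcodes was therefore replaced by a test over the 2 sorts.

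The 17749 sequences comprise 17745 fragments of 159 bases, which encode 53 residues without a stop codon, and 4 nested read lengths of a construct without an insert. Fragments were translated with Biopython 1.88 and joined into regions with networkx 3.6.1 wherever their translations overlapped by at least 27 residues. This gave 902 regions with a median of 16 fragments. A region stands in for a protein, and regions of one protein that do not overlap count separately. Similar sequences that are not identical also form separate regions. Examples are those with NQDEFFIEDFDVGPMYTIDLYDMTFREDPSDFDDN and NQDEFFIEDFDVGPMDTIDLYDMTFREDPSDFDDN. Regions are therefore not all independent, and p-values and intervals that rest on them may be too small or too narrow. One repetitive region of 45 fragments, whose positions were ambiguous, was left out of the comparison of neighbours. Gene and species names are not paired with the sequences in the files used here, so the comparison of species, the lists of complexes fixed before the data were examined and the naming of genes are not analysed here. Regions are identified by their peptide.

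Fragments with at least 5000 reads in each sort were kept, 12763 of the 16962 seen in both. This minimum was not neutral to activity in the smaller sort. Median activity there was 1713 under 1000 reads against 5521 with at least 5000. In the larger sort the medians were 5327 and 5253. Activities were taken to log2 and quantile-normalized between the sorts, because the 2 sorts differed in range. The baseline was the mean, per sort, of the 1386 fragments in the tenth with the lowest count of D, E, F, W, Y and L minus K and R (score of 16 or less), a rule fixed before the data were examined that does not use activity. These fragments belong to a library of predicted activation domains, so the baseline is not a set without activity. Each fragment's mean difference from the baseline was tested one-sided with limma 3.58.1 in R 4.3.3, moderated over fragments, and adjusted by Benjamini-Hochberg at 0.05.

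The read minimum, the quantile normalization and the constant spread were chosen after the data had been examined. The read minimum was set from the correlation of the sorts. At a minimum of 1000 reads, 6 combinations of scaling and depth trend had been counted first. They called between 2997 and 7450 of 15623 fragments, and the form chosen lies among the more permissive.

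Correlations with composition used the counts of 20 residues, net charge (K and R minus D and E) and the sum of W, F, Y and L. Spearman rho was computed across fragments, with a 95% interval from 1000 bootstrap draws of regions. A two-sided permutation test with 100000 resamples was run on region means, adjusted by Benjamini-Hochberg over the 22 properties. Differences between the N-terminal and C-terminal 26 residues, and between overlapping and separate fragments, carry 95% bootstrap intervals over regions. Fragments overlap, so correlations across fragments do not count independent replicates. Single-residue steps were fitted by least squares with 10000 sign flips of whole regions. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

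The rule for named items took the 20 regions whose strongest fragment was highest, among fragments above the baseline and in the highest 10% of each sort, and the 10 regions with the lowest maximum among those with at least 5 measured fragments. The equal split by species and the minimum of barcodes in that rule could not be applied.

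The limma step was tested on 12763 simulated fragments with the noise of the data. Among 50 fragments raised at each size, it recovered 0% at log2 0.5, 80% at 1, 98% at 2 and 100% at 3, and called 0 unchanged fragments. With 6382 raised by 1.5 it called 105 unchanged ones. Each unchanged fragment had a true value of 0, and few were raised in the first simulation. In the data 7115 of 12763 were called, which loosens the adjusted threshold, and a fragment at log2 0.23 passed. The rates of the first simulation therefore do not describe the test as applied. The permutation on region means recovered F when only F was given an effect. In a separate simulation without any effect it passed 0 properties. How many other properties passed alongside F was not counted, so selectivity among correlated properties was not tested. The step model recovered both simulated residues of log2 0.1 over 9944 steps and called 1 other.

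Reads over fragments totalled 322397626 in the larger sort, with a median of 15366.5 per fragment, and 271072648 in the smaller, with a median of 11637. Reads carry PCR copies, so they overstate the number of cells behind a value. Alternatives covered the read minimum, the baseline, the scaling of the sorts, the spread and each sort alone.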

Results

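Activation domains are the parts of a protein that switch on transcription when they are brought to a promoter. The series measured such activity for fragments of proteins that are not transcription factors, from plants and yeast, in a GFP reporter assay. The 16 libraries comprised 8 gates of GFP level, with 2 samples per gate, one from each sort. Activity was read as the authors' score for each fragment and sort. The larger sort held 322397626 reads over 17636 fragments and the smaller 271072648 over 17011. The fragments carried a mean of 6.90 D, 6.14 E, 4.89 L and 3.40 F among 53 residues, and a mean net charge of -10.3.

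The first comparison set the 2 sorts against each other. Fragments ranked alike in both sorts, with a Spearman rho of 0.936 and a Pearson r of 0.910 on log2 values across 12763 fragments, which are not independent of one another. The minimum of 5000 reads behind these values was itself set from this correlation, and over all 16962 fragments seen in both sorts rho was 0.751 and r 0.704. Active fragments were ranked most alike. Among the 2535 fragments between 9904 and 17998 in the smaller sort, rho was 0.824, and their median activity in the larger sort was 8774. Among the 2095 fragments between 1051 and 1828 in the smaller sort, rho was -0.11, and their values in the larger sort spread from 2991 to 4000 between the quartiles around a median of 3478. These bands follow the gate values and were chosen after the data had been examined. In that band the 2 sorts did not rank fragments alike, though a narrow band lowers any correlation. The larger sort also covered a narrower range, with an SD of 0.53 on the log2 scale against 1.04.

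**Figure D1:**
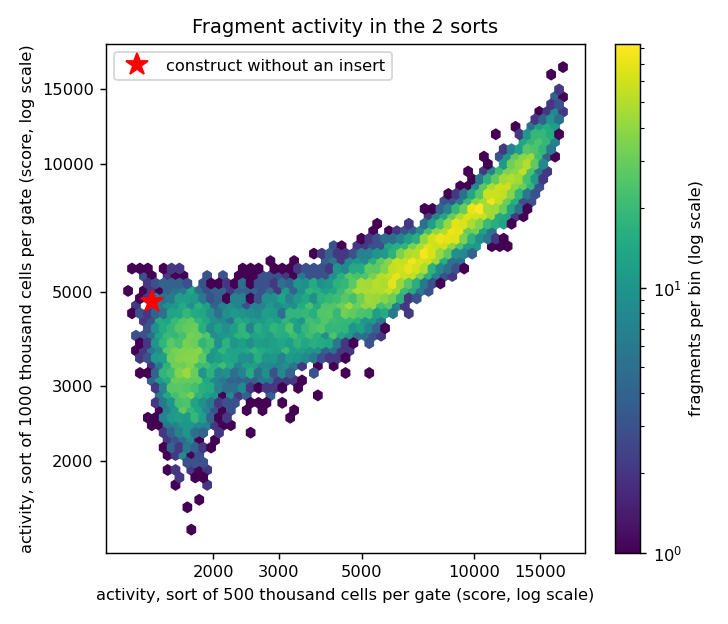
Activity of 12763 fragments in the smaller sort (x axis, score, log scale) and the larger sort (y axis, score, log scale), with the colour giving fragments per bin and the star the construct without an insert. The 2 sorts rise together above 4338 on the x axis, while fragments below 1828 form a vertical cloud without a common order.

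The same peptide encoded by different DNA gave an internal measure of repeatability. For 54 such pairs from 6 regions, the median absolute difference was 0.26 on the log2 scale in the larger sort and 0.12 in the smaller. Pearson r within pairs was 0.789 and 0.982. One of the 54 pairs differed by more than 1 in the larger sort, and 0 did in the smaller.

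The construct without an insert served as the only unfused reference. It carried the recognition sites TTAATTAA and GGCGCGCC, and the labels describe a PacI digest meant to remove such plasmids because they give inactive factors. Its activity was 4741 in the larger sort, above 39.8% of the 12763 fragments, and 1369 in the smaller, above 0.431% of them. Its 4 read lengths varied between 4715 and 4811 and between 1361 and 1387 on 134693 to 410811 reads each. The read lengths are nested reads of one construct within a sort, so they do not measure the variation between sorts. No fragment carried a stop codon, so truncated fragments were not compared.

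The second comparison asked which fragments activated the reporter more than fragments of low acidic and aromatic content. Against that baseline 7115 of 12763 fragments, or 55.7%, were higher (limma, one-sided, adjusted p under 0.05, n = 2 sorts). Of these, 3010 exceeded the baseline by more than 1 on the log2 scale. The 55.7% holds for fragments with at least 5000 reads in each sort. At minimums of 50 and 1 reads the share was 43.1% and 41.0%. In a two-sided test 6942 fragments were higher and 2769 lower. The baseline itself lay at a geometric mean of 4481 in the larger sort and 3596 in the smaller. Before normalization, the baseline fragments had SDs of 0.43 in the larger sort and 0.89 in the smaller on the log2 scale. The test took their mean as fixed, so this spread does not enter the p-values. In the smaller sort, 24.0% of them lay between 4338 and 6613 and 13.6% between 6613 and 9904. A fragment called above the baseline thus exceeds the baseline mean, not necessarily the range of the baseline fragments. On the normalized log2 scale the insert-free construct lay 0.19 above the baseline mean in the larger sort and at -1.23 in the smaller. With the insert-free construct as the reference, the one-sided count fell to 1968, or 15.4%, all among the 7115, and the two-sided limma test called 0 at an adjusted p of 0.05 and 3650 at an unadjusted one. The disagreement of this reference between the sorts enters the spread that the test uses for every fragment. These counts therefore do not show that fewer fragments were active. Without quantile normalization 4934 fragments, or 38.7%, were above the baseline, and the two-sided test called 4571 higher and 1516 lower.

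The third comparison took regions as the unit. At least 1 fragment above the baseline was found in 626 of 837 regions, or 74.8% (exact binomial interval 71.7% to 77.7%, counting error only). Since 1 fragment sufficed and 55.7% of all fragments were called, regions with more measured fragments pass more easily. The share is therefore not a rate of proteins that hold an activation domain. The share was 31.9% against the insert-free construct and 59.5% without quantile normalization. Of the 686 regions with at least 5 measured fragments, 97 had every fragment above the baseline, 133 had none and 456 were mixed. Within such a region the strongest and weakest fragments differed by a median of 1.32 on the log2 scale. In 136 of them the difference exceeded 2. Over all 837 regions, differences between region means made up 62.5% of the variance of log2 activity. This share was not corrected for region size, and regions with few fragments raise it.

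The leading fragments of the 20 strongest regions, by the mean over both sorts, reached 12364 to 16866 in the larger sort and 16220 to 17301 in the smaller. These fragments were 1.84 to 2.09 above the baseline on the log2 scale, with SEs of 0.08 to 0.09 and an adjusted limma p of 0.000923 in each case (n = 2 sorts). The SEs lie near a floor set by the moderation, whose prior SD was 0.13 on 2.51 degrees of freedom. They were also computed after quantile normalization, so they do not measure how far the scores of the 2 sorts differ. All of them were also called in every alternative setting in which they were tested. They held a mean of 12.4 W, F, Y and L residues, against 10.7 over all fragments, and 13.8 D and E residues, against 12.8. Phenylalanine occurred at least 3 times in 17 of the 20, against 68.7% of all fragments. Tryptophan was present in 11, against 53.8%, with a mean of 0.85 in both, so it did not set the 20 apart. Such differences were not tested, since the 20 were picked by activity.

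The highest value belonged to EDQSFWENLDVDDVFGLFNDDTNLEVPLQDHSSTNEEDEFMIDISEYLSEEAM, with an activity of 16866 in the larger sort and 17301 in the smaller on 7630 and 15638 reads. It carried 9 D, 9 E and no K or R. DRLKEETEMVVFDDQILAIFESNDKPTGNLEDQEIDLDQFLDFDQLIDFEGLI followed at 13937 and 17134, and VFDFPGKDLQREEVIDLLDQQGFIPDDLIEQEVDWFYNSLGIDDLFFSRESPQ at 14406 and 17107. A leucine-rich fragment, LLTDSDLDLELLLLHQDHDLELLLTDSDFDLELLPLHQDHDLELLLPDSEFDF, reached 14327 and 16582 with 20 L and without W or Y. A glycine-rich repeat, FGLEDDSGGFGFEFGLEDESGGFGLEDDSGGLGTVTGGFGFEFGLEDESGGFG, reached 12647 and 16253 with 9 F, and all 52 measured fragments of its region were above the baseline. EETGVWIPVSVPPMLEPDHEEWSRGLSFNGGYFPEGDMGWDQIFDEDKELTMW, with 4 W, reached 13465 and 16220.

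Overlapping fragments placed activity within some of these regions. In the region of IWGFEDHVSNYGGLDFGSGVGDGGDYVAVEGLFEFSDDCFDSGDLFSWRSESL, 23 of 34 fragments were above the baseline in an unbroken run that shared 31 residues, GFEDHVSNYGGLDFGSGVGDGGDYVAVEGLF, and the fragments that started nearer to the N-terminus were not called. The run went on to the last measured fragment, so the N-terminal edge of this stretch is where measurement ended. Only its C-terminal edge was bounded by fragments that were not called. In the region of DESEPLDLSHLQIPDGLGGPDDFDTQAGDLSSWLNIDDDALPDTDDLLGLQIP all 28 measured fragments were above it, and in that of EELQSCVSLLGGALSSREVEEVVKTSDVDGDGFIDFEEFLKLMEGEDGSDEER all 20 were, so the fragments set no bound there. The shared stretch was not tested alone.

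**Figure D2:**
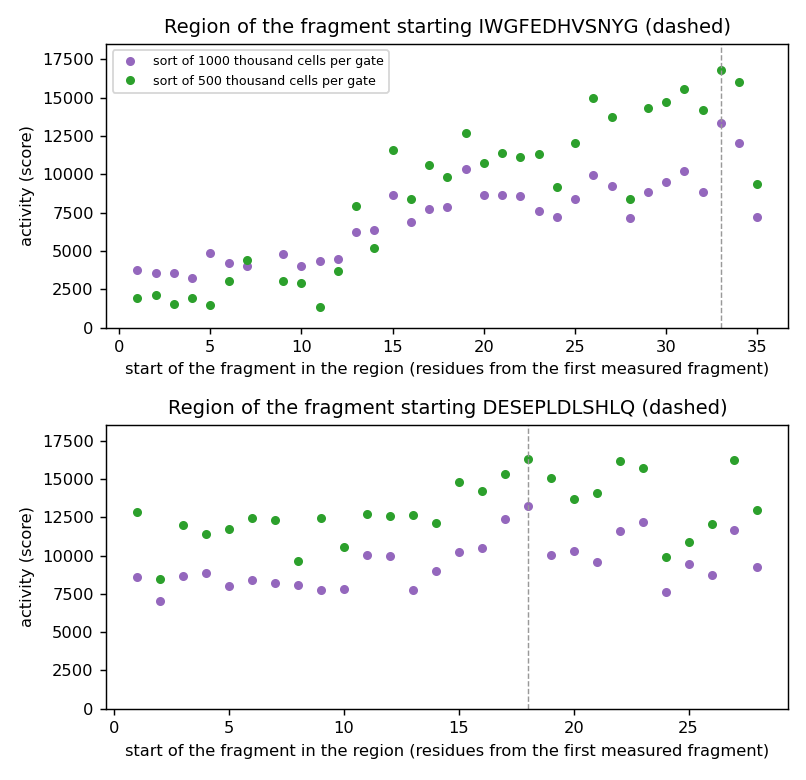
Activity (score) of each measured fragment by its start position in residues, for the larger and the smaller sort, in 2 of the 20 strongest regions, with the strongest fragment dashed. In the upper region 23 of 34 fragments were above the baseline, all to the right, and in the lower region all 28 were.

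The 10 regions with the lowest maxima each had 5 to 8 measured fragments, while regions had a median of 16 before the read minimum. A maximum over few fragments tends to be lower, so the rule favours regions with few. The best fragments of the 10 regions, by the mean over both sorts, lay at 2718 to 3997 in the larger sort and 1472 to 3025 in the smaller. These fragments lay between -0.75 and -0.54 on the log2 scale relative to the baseline, and 9 of the 10 were lower than it in the two-sided limma test. The 10 were picked by these same values, so that count adds no support. The differences in residues given next were not tested. They were as acidic as the strongest regions, with a mean net charge of -12.1 against -12.3 and 14.2 D and E residues. They held a mean of 9.0 W, F, Y and L residues and 0.30 W, against 10.7 and 0.85 over all fragments. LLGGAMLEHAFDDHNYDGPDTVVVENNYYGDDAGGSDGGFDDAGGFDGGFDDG was one, at 3671 and 1602 on 37202 and 54684 reads. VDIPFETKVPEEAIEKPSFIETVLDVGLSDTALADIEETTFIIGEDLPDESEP was another, at 3937 and 1472.

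The fourth comparison related residue content to activity. Activity rose with the sum of W, F, Y and L (rho 0.271 over the means of 837 regions), with F (0.228), P (0.177) and W (0.101), and fell with E (-0.139), K (-0.118), I (-0.105) and V (-0.0813). Permutation p-values were 1e-05 for the first 3, the smallest that 100000 resamples can give (adjusted 7.33e-05). They were 0.00351 for W, 8e-05 for E, 0.000630 for K, 0.00204 for I and 0.0181 for V, with adjusted values of 0.0110, 0.000440, 0.00277, 0.00748 and 0.0497. These 8 of 22 properties passed. Within the sum, L (0.0313, permutation p = 0.365, adjusted 0.535) and Y (0.00765, permutation p = 0.827, adjusted 0.957) did not pass on their own. With the larger sort alone V no longer passed, and at 20000 reads neither I nor W did. G passed newly with the larger sort alone (rho 0.0857, adjusted permutation p = 0.0351). S did so at 20000 reads (rho 0.116, adjusted permutation p = 0.00921).

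Levels differed along phenylalanine content. The 1623 fragments with 0 to 1 F had a median activity of 3658 in the smaller sort and 39.2% lay above the baseline, whereas the 1571 with 6 to 13 F had a median of 8095 and 75.2%. The means of their regions were -0.02 ± 0.62 (SD, n = 202 regions) and 0.64 ± 0.65 (SD, n = 133) on the log2 scale. Lysine ran the other way, with 62.8% of fragments without K above the baseline and 33.4% of those with 5 to 10. For proline, 47.9% of fragments without it and 68.0% of those with 5 to 11 were above.

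No rise of activity with acidic residues was detected over region means of this acidic library. Aspartate gave a rho of -0.00311 over region means (permutation p = 0.928, adjusted 0.988). Across fragments, rho was 0.0505 with an interval from -0.0134 to 0.110. Net charge had opposite signs at the 2 levels, -0.0687 across fragments (-0.134 to -0.00627) and 0.0655 over region means (permutation p = 0.0586, adjusted 0.117). Arginine fell across fragments, at -0.112 (-0.168 to -0.0514), but missed the threshold over region means, at -0.0369 (permutation p = 0.290, adjusted 0.455). For W the interval across fragments, -0.0134 to 0.121, included 0.

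**Figure D3:**
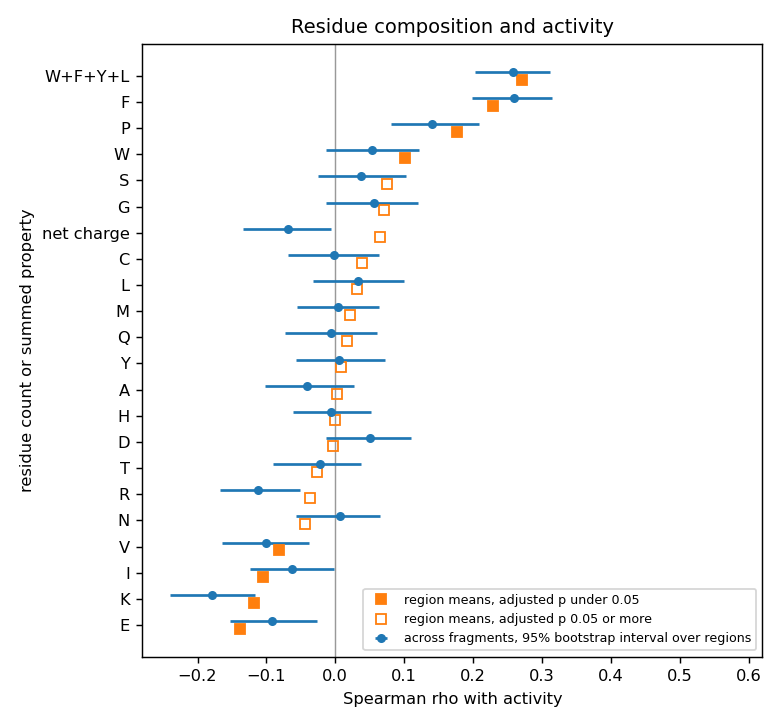
Spearman rho with activity (x axis) of 20 residue counts, net charge and the sum of W, F, Y and L (y axis), across 12763 fragments with 95% bootstrap intervals over regions (circles) and over 837 region means (squares, filled where the adjusted permutation p was under 0.05). The sum of W, F, Y and L lies farthest right at 0.271, and E farthest left among the region means at -0.139.

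The fifth comparison asked where in the fragment these residues lay. W, F, Y and L went with activity more strongly in the C-terminal 26 residues (rho 0.204, 0.155 to 0.252) than in the N-terminal 26 (0.117, 0.0687 to 0.160), a difference of 0.0873 with a 95% interval from 0.0262 to 0.157. Acidic residues near the C-terminus went with lower activity (-0.0957, -0.146 to -0.0355), and those near the N-terminus gave 0.0265 (-0.0285 to 0.0837). That difference was -0.122 (-0.188 to -0.0521). These correlations run across fragments and mix differences between regions with those within them. At 20000 reads the interval of the hydrophobic difference, 0.0767, included 0.

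The last comparison used overlapping fragments as neighbours. Activity of fragments whose starts lay 1 residue apart correlated with a Pearson r of 0.876 over 10110 pairs, with a median absolute difference of 0.20 on the log2 scale. The correlation was 0.594 at 10 residues, 0.379 at 26 and -0.0108 at 53, where fragments no longer overlap. Pairs with a distance of 1 to 26 residues gave 0.618 (0.582 to 0.651) among 836 regions, a number that includes any region without such a pair. Non-overlapping pairs of the same region gave 0.226 (-0.460 to 0.588), from only 21 regions. The difference was 0.392 (95% bootstrap interval 0.0260 to 1.07). At 20000 reads, with 15 regions holding non-overlapping pairs, it was 0.233 with an interval that included 0.

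**Figure D4:**
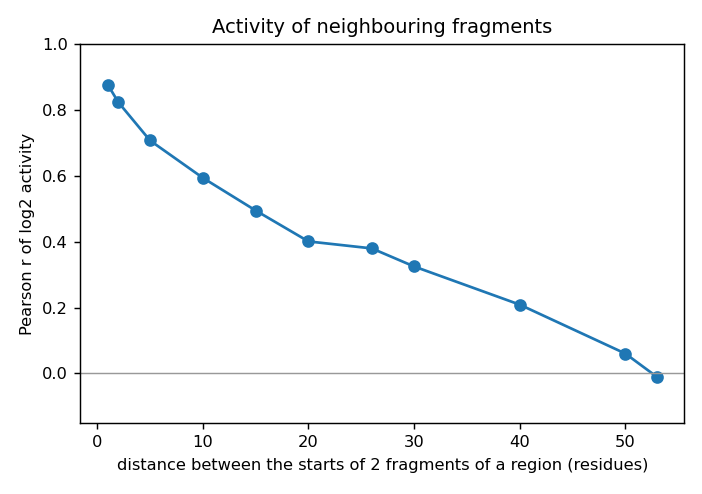
Pearson r of log2 activity between fragments of a region (y axis) by the distance between their starts in residues (x axis). It falls from 0.876 at 1 residue to 0.379 at 26 and -0.0108 at 53.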

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

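The tests on spread by depth and on the barcode table were chosen only after the results had been seen. The data outside the main measurement were the read numbers in the table by barcode. They summed to 32.6 times the reads of the fragment table in the larger sort and to 19.8 times in the smaller. Of the entries over 100 reads, 26.6% (17.7% in the larger sort and 53.6% in the smaller) exceeded the reads left for all barcodes of their fragment, which argues against plain counts of the reads in the fragment table. Another explanation is that totals per fragment were filled into barcode entries, but the 0.000311% that exceeded the entry without a barcode of their fragment decide nothing, since that entry held 64.0% and 64.7% of the reads and ordinary counts would stay below it too. No biological explanation was tested, and how the table was made stays open.

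The spread of the larger sort did not change with depth in one direction. Over all fragments, the SD of log2 activity in the tenth with the fewest reads (11 to 4539) was 1.29 times that in the tenth with the most (95% bootstrap interval 1.20 to 1.37), as sampling noise of reads would give, whereas among fragments with at least 1000 reads in each sort it was 0.664 times (0.623 to 0.704), the opposite of what sampling noise alone gives. A candidate explanation for the narrower spread is background reads shared by all fragments, and the slope of the larger sort's log2 activity on the other sort was 0.410 times as steep in the tenth with the fewest of these reads (0.377 to 0.441), although noise in the other sort can lower that slope too. Fragments under 1000 reads lay nearer to the insert-free construct than those with at least 5000 in the smaller sort, with a median absolute log2 distance that differed by -1.59 (-1.62 to -1.57), but farther from it in the larger, by 0.20 (0.17 to 0.25), which the wider scatter at few reads can give with or without background. Median activity in the larger sort was no lower where reads were few, at 5308 in the tenth with the fewest of at least 1000 reads against 4816 in that with the most, and at 5327 under 1000 reads against 5253 with at least 5000, whereas in the smaller it was 1713 against 5521; the cause stays open, background included, and no biological explanation was tested.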

How the results depend on the processing

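The read minimums of 1000 and 20000, the insert-free reference, the scalings of the sorts and the spread changing with depth were chosen after the data had been examined. Fragments above the baseline numbered 7115, and 1968 against the insert-free construct and 2551 at 20000 reads, where only 4199 were tested. The other 7 settings gave 4934 to 7448. Among them, 50 reads gave 7078 of 16431 (43.1%, 6231 of them among the 7115) and 1 read 6949 of 16962 (41.0%, 6119 among them), against 55.7%. The share of regions with such a fragment was 74.8%, and 68.3% at 50 reads, 65.4% at 1 read, 31.9% against the insert-free construct and 59.5% without quantile normalization. The insert-free construct lay 0.19 above the baseline in the larger sort and at -1.23 in the smaller. As the reference, it carries that disagreement into the spread between sorts of every fragment. The lower values against it therefore do not show that fewer fragments were active. The cause of the other moves was not tested. The rank correlation of the sorts, 0.936, was 0.751 at 1 read, 0.788 at 50, 0.854 at 1000 and 0.963 at 20000; the fragments compared change with the minimum too, so depth alone was not tested. The share of fragments above the baseline mean, a value with no test since 1 sort leaves no residual, was 64.4% for both sorts and 65.7% to 66.0% with either left out. The difference between C- and N-terminal W, F, Y and L, 0.0767, and that between overlapping and separate fragments, 0.233, lost their threshold at 20000 reads, where fewer fragments were tested. With either sort left out, both kept their side of it, and 8 of 22 properties passed. With the smaller sort left out, G stood among the 8 in place of V. Of the further values for single properties, 94 kept their direction and side of the threshold, 3 fell short of it and 2 passed it newly. Another 11 changed sign, each for a property that did not pass, and the cause was not tested. With either sort left out, rho ranged from -0.00647 to 0.0147 for A, -0.0201 to 0.0235 for D, -0.00671 to 0.00515 for H and -0.00277 to 0.0184 for Y. A was -0.00714 and D 0.000907 at 1000 reads, A was -0.000241 without quantile normalization, and at 20000 reads A was -0.0162, H 0.00720, M -0.0247 and T 0.0168. Not run were the gate trend and its alternatives, minimum barcodes, the median over barcodes, the share of upper gates, unscaled gates, truncated fragments, species and gene lists, which need values not used here.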

Other observations

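The 3 tests of single-residue steps were chosen before their results were seen; the grid of charge and hydrophobic content was chosen afterwards and carries no test. Mean activity was highest where acidity and W, F, Y and L content came together. Among the most acidic fragments (net charge of -11 or below), those with at most 10 of these residues had a mean of 0.11 ± 0.70 (SD over 386 regions) on the log2 scale above the baseline, and those with more than 12 had 0.72 ± 0.75 (139 regions). Among the least acidic (above -9), the means were 0.03 ± 0.58 (280 regions) and 0.33 ± 0.67 (185 regions). Above the baseline were 42.9% and 77.5% of the acidic fragments, and 41.9% and 58.3% of the least acidic. The spread between regions was as large as the differences, and whether the gain differs between the charge classes was not tested.

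Fragments tiled by 1 residue allow a comparison in which 1 residue is lost at the N-terminus and 1 gained at the C-terminus. Over 9944 such steps in 777 regions, the hypothesis that a single terminal residue goes with activity was tested with 40 coefficients, each relative to the average residue. 18 passed, 10 for a gained and 8 for a lost residue. Gaining F went with a change of 0.17 on the log2 scale (95% interval 0.13 to 0.21), W with 0.15, L with 0.13 and I with 0.10, while K gave -0.16, A -0.15 and R -0.10. Losing W gave -0.18 and F -0.10, and losing K gave 0.13 and R 0.11. Gained D and E gave 0.01 each and did not pass (adjusted sign-flip permutation p = 0.658 and 0.720). Losing D gave -0.04 (-0.07 to -0.02) and passed (adjusted sign-flip permutation p = 0.00450), and losing E gave -0.01 and did not (0.728). Losing L gave -0.05 and passed, whereas losing I (-0.01, adjusted sign-flip permutation p = 0.728) or A (-0.02, 0.507) did not. Gained I had a positive sign here, whereas I had a negative one across region means. Gained D and E did not pass here, whereas acidic residues in the C-terminal 26 gave a rho of -0.0957 across fragments. P, positive across region means (0.177), gave -0.01 both gained and lost and did not pass (adjusted sign-flip permutation p = 0.728 each).

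Technical causes were weighed for the gained F. With the change in reads of both sorts as covariates its coefficient was 0.167 (0.125 to 0.207), and with the change in GC count 0.168 (0.125 to 0.209), against 0.17 without either. Both intervals lie above 50% of that value, which argues against depth or base composition as the cause. Both sorts gave the same sign for F, 0.10 in the larger and 0.24 in the smaller. The coefficients may reflect the residue itself or what it does to the new terminus next to the vector, and the design does not separate these.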
